A study of Glycine max with 4 samples.

How the data were processed

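The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of embryos from soybean (Glycine max, cultivar Williams 82) at the mid-maturation stage of seed development. The antibody was raised against a peptide of GLYMA.08G357600. The submitters' file naming ties this gene to ABI3, a B3-domain transcription factor of seed maturation. The 4 ChIP samples are 2 biological replicates with 2 technical replicates each. A peak list was used for 1 sample of each biological replicate, and the 2 other samples had no file of their own here. Whether a list was made from 1 technical replicate or from both is not stated in the sources used here, although the file naming hints at both. Input controls are named in the study design but were not analysed here as separate samples.

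Per the submitters' processing notes, the authors used Bowtie 0.12.7 and MACS2. Alignment settings, the peak threshold, the MACS2 version and the genome build are not given in the sources used here. The deposited lists are in the narrowPeak layout, without a header. The authors' fold values are ratios of the ChIP signal to the local background at the summit. The authors' p-value and q-value columns hold −log10 values at the summit. The deposited score column is the −log10 q-value multiplied by 10 and truncated to a whole number, and was not used further. Start, end and summit positions count bases and are printed here from 1. No rows overlapped within a list, so each row is 1 region.

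The lists place regions under 2 sets of names in 1 numbering, 20 chromosomes with the prefix Chr and 20 with the prefix Gm, plus scaffolds. All positions below are given with their prefix. The gene table supplied as a reference is of the assembly Glycine_max_v4.0. In a check of the build, 13.5% of the 608 shared regions with Chr names had a summit within 1000 bp of the outer side of a protein-coding gene of that table, against 14.3% on average when all summits were moved by 1 of 1000 random distances (one-sided permutation p = 0.74). For the 280 with Gm names the share was 17.9% against 14.5% (one-sided permutation p = 0.066). In addition, 4 and 5 of these regions lay more than 100000 bp past the last gene of their chromosome. The table was therefore not used to place genes. Without a genome sequence and an annotation of the same build, the planned results on transcription starts, motifs and gene lists were not computed, and the rule for named genes could be applied only to regions. The position of GLYMA.08G357600 itself was not analysed here. The named regions are the 20 shared regions with the best worse rank, which is the larger of the 2 within-list ranks by −log10 q.

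Regions were called shared where they overlapped by at least 1 bp. The count was compared with 1000 random placements of the replicate 1 regions on their own chromosomes. The last called position stood in for the length of each chromosome, since lengths are not given. Shares carry exact (Clopper-Pearson) 95% binomial intervals. Fold enrichment was compared across shared regions with Pearson's r on log2 values and with Spearman's rho. Shared and unshared regions were compared by their median percentile of −log10 q within 1 list. Both used 100000 permutations. These tests treat regions as units, and regions are not independent replicates. With 1 list for each of 2 biological replicates, no test over replicates was run.

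MACS2 computes fold enrichment as the fragment count at the summit plus 1, divided by the local background plus 1. It computes the p-value as the Poisson upper tail. Solving both for each row gave a whole fragment count that met the deposited −log10 p-value within 0.001 in 100% of the rows of each list. The depth behind each region was taken from these counts. They are fragments after the authors' processing, so Poisson intervals and shares cover counting error only. A region has high local background where the recovered background is over 2 times the lowest in its list. The total number of reads per library is not in the lists.

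Regions under the Chr and Gm names were linked where they kept their spacing, in the same or the reversed order. Links are chains of at least 8 regions of both replicates, with neighbours at most 2000000 bp apart and with distances that differ by at most 500 bp plus 1% of the distance. This rule was chosen after 10 settings had been tried on these lists, by the separation of pairs of equal number from the 380 pairs of unequal number, which served as the chance level. Their mean is not an even chance level, since their links were concentrated on 5 chromosomes. The settings gave 292 to 516 links in pairs of equal number, with 0.474 to 44.1 expected by chance and unequal pairs holding 2.61 to 64.4% of all links, so the number of links depends on the rule. For each setting, the total over pairs of equal number was compared with 100000 shuffles of the Gm chromosome numbers. On simulated chromosomes, 47.5% of the planted pairs were linked and 3.61% of the links were wrong. Unrelated simulated chromosomes held 0.4 links on average. The simulated chromosomes held fewer regions than the chromosomes of these lists on average, so the rate of wrong links in these lists may differ. On simulated lists, 601 regions were found shared where 600 of 900 had been planted, and 100% of the simulated fragment counts were recovered. Linking, its settings, the positions along chromosomes, the neighbour counts and the local background were chosen after the data were examined. Sharing, ranks and their alternatives (reciprocal 50% overlap, summits within 100 bp, −log10 q of at least 5, equal list lengths, chromosomes only) were fixed before the data were examined. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.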

Results

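Binding of GLYMA.08G357600 was profiled by ChIP-seq in mid-maturation soybean embryos, the stage at which seeds lay down protein and oil reserves. The study asked where in the genome this transcription factor is bound. The design holds 1 group, 1 antibody and 2 biological replicates, so the comparisons are between the 2 replicates, between positions along the chromosomes, and between the 2 sets of chromosome names used in the lists. The list of replicate 1 held 939 regions that covered 294 kb, and that of replicate 2 held 2460 regions that covered 821 kb. The regions were narrow, with a median width of 291 bp in replicate 1 and 310 bp in replicate 2. Median fold enrichment at the summit, the authors' own value for each region, was 5.97 in replicate 1 and 6.202 in replicate 2, with maxima of 19.6 and 30.0. The median summit held 28 fragments in replicate 1 and 30 in replicate 2, over a lowest background of 3.69 and 3.84 fragments per position. The fewest fragments at a called summit were 17 in replicate 1 and 16 in replicate 2. The lowest −log10 q-value was 2.45 in replicate 1 and 2.27 in replicate 2. These belonged to other regions, with 194 and 179 fragments on a high local background.

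Nearly every region bound in replicate 1 was also called in replicate 2. Of the 939 regions of replicate 1, 892 overlapped a region of replicate 2 (95% interval of the share 93.4 to 96.3%). Random placement gave 1.09 shared regions on average and at most 6 in 1000 draws (one-sided permutation p = 0.001, the smallest that 1000 draws can give). When the regions of replicate 1 were instead moved by up to 1 Mb, which keeps them in the same part of the chromosome, 25.4 were shared on average and at most 38. The summits of shared regions lay a median of 29 bp apart, and 93.8% lay within 100 bp. The same 892 regions were 36.3% of the list of replicate 2 (95% interval 34.4 to 38.2%). This left 1568 regions of replicate 2 that replicate 1 did not call under the same name. Some of these were linked to a region of the other name that replicate 1 called, as described below. With Chr names only, 608 of 648 regions of replicate 1 were shared, and with Gm names only, 280 of 287.

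Shared regions were the stronger part of the list of replicate 2 and nearly the whole list of replicate 1. Within replicate 2, shared regions had a median percentile of 80.5 by −log10 q and unshared regions one of 35.4, a difference of 45.1 points (two-sided permutation p = 1e-05, the smallest that the permutations can give). With each list divided into 4 classes by −log10 q, the strongest class of replicate 2 had 524 of 614 regions shared (85.3%), and the weakest class 48 of 629 (7.63%). Within replicate 1, the median percentile was 53.7 for the 892 shared regions and 15.5 for the 47 unshared regions (difference 38.2 points, two-sided permutation p = 1e-05). In the strongest class of replicate 1, 235 of 236 regions were shared, and in the weakest class 182 of 216 (84.3%). The unshared regions of replicate 2 had a median fold enrichment of 5.58, against 8.48 for the shared regions of that list. Cutting the list of replicate 2 to its strongest 939 regions left 655 shared regions (69.8%).

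The 2 replicates ordered the shared regions alike. Across the 892 shared regions, fold enrichment gave a Spearman rho of 0.62 and a Pearson r of 0.73 on the log2 scale (two-sided permutation p = 1e-05 for each, the smallest that the permutations can give, and 1e-05 after Benjamini-Hochberg adjustment over the 6 settings tried). Within the 608 shared regions with Chr names rho was 0.62, and within the 280 with Gm names it was 0.67. These are correlations across regions, which are not independent replicates. The 2 name sets list some of the same places, so their values of rho are not independent of each other.

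**Figure D1:**
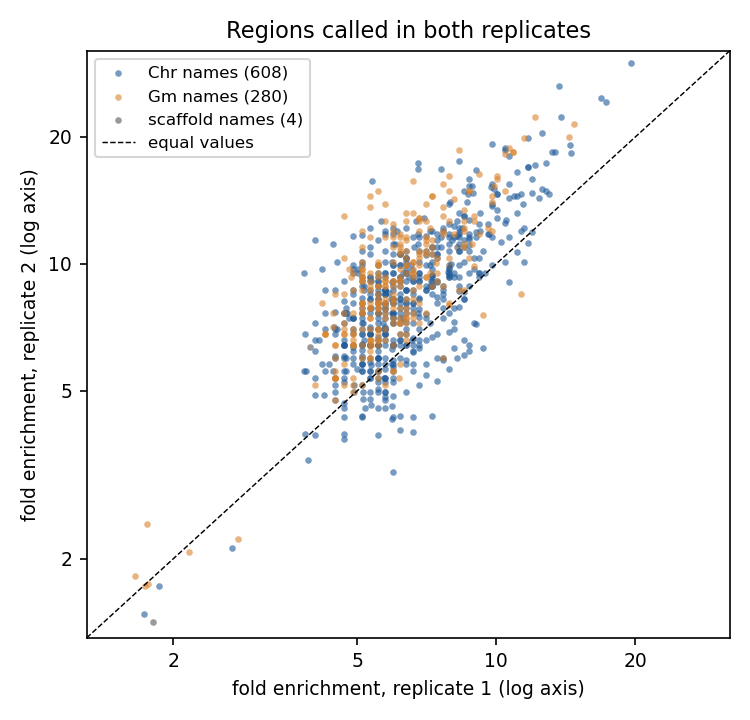
Fold enrichment at the summit of each shared region in replicate 1 (x axis) and replicate 2 (y axis), both on log axes without unit; each point is 1 region, coloured by the prefix of its chromosome name, and the dashed line marks equal values. The 892 points rise together (Spearman rho 0.62), and a small group lies near a fold of 2 in both replicates.

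The strongest region of both lists lay on chromosome 10. Of the 20 shared regions with the best rank in both lists, 16 had Chr names and 4 had Gm names, and they lay on 8 chromosomes. The leading region was Chr chromosome 10, 42601376 to 42601929, first in both lists. Its fold enrichment was 19.6 in replicate 1, from 91 fragments at the summit (95% Poisson interval 73.3 to 112), and 30.0 in replicate 2, from 144 fragments (121 to 170). The next was Chr chromosome 20, 43441481 to 43441918, with a fold of 16.8 in replicate 1 and 24.7 in replicate 2. It was followed by Chr chromosome 3, 37825557 to 37826167, with 17.3 and 24.2. Another region of chromosome 10, 47482903 to 47483475 under the Chr names, had a fold of 13.7 in replicate 1 and 26.4 in replicate 2. Over all 20 regions, fold enrichment ran from 10.4 to 19.6 in replicate 1 and from 16.95 to 30.0 in replicate 2, and no summit pair lay more than 109 bp apart. The build of these positions is not given in the sources used here, and the genes beside them were not analysed here.

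Shared regions were concentrated toward the ends of the chromosomes. Of the 608 shared regions with Chr names, 433 lay in the outer 20% at either end of their chromosome (71.2%, 95% interval 67.4 to 74.8%), where an even spread would put 40% (one-sided permutation p = 0.001, the smallest that 1000 draws can give). An even spread takes no account of where genes, or sequence to which reads can be aligned, lie, and neither was analysed here. The p-value therefore does not show an end preference of this factor. With Gm names the share in the outer parts was 71.4% (65.8 to 76.6%). The 2 name sets list some of the same places, as described below, so the 2 shares are not independent. The middle of the chromosomes was sparse: with chromosomes divided into 10 equal bins, bin 6 held 2.63% of the shared regions with Chr names and bin 10 held 22.9%. The 828 regions of replicate 2 with Chr names that were not shared had 68.5% in the same outer parts (65.2 to 71.6%). The number of shared regions also differed between chromosomes (chi-square 49.3 against an allotment by length, p = 0.0002 from 100000 simulated allotments). The allotment took each region as independent and ignored the uneven spread within chromosomes, so a difference beyond that spread is not shown. Chromosomes 11, 8 and 13 under the Chr names held 0.99, 0.97 and 0.96 shared regions per Mb, and chromosomes 1 and 14 held 0.39 and 0.43, with a mean of 0.65. The last called position stood in for chromosome length in these values.

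**Figure D2:**
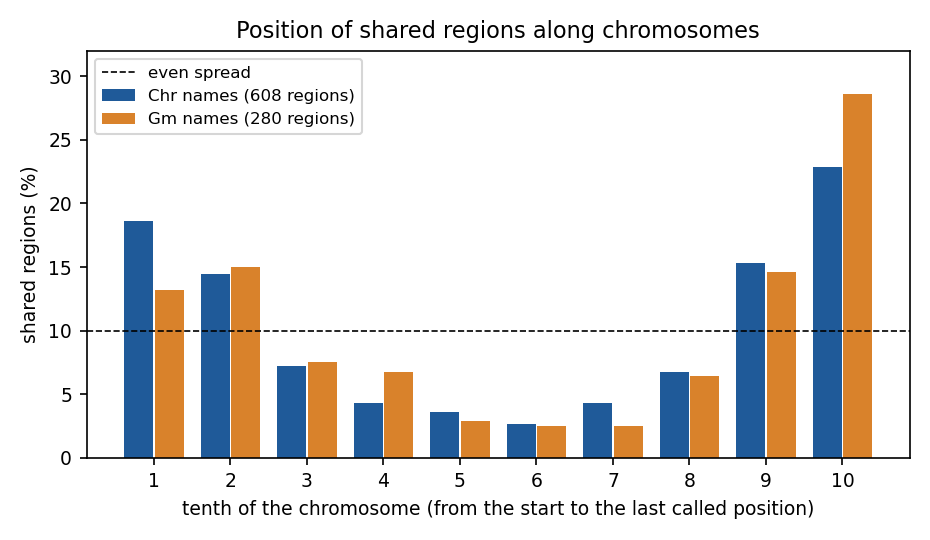
Percent of shared regions (y axis) in each of 10 equal bins of the chromosome (x axis, from the start to the last called position), as bars for Chr and Gm names; the dashed line marks an even spread of 10%. Bins 1 and 10 held 18.6% and 22.9% of the regions with Chr names, and bin 6 held 2.63%.

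Some shared regions came in close groups. Of the 608 with Chr names, 55 had another shared summit within 10 kb (9.05%, 95% interval 6.89 to 11.6%), against 12.8 on average after random moves of up to 1 Mb (one-sided permutation p = 0.001, the smallest that 1000 draws can give). With Gm names the count was 23 of 280, against 2.91 on average, although the 2 name sets list some of the same places. The only run of 3 or more shared regions with Chr names and gaps of at most 10 kb was on chromosome 18, 2730111 to 2737115, with 3 regions and a median fold of 5.97 in replicate 1. In the whole list of replicate 2, shared regions included, 146 of 1436 regions with Chr names had such a neighbour, against 72.0 on average after random moves.

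The Chr and Gm names listed many of the same runs of regions. Across both replicates there were 1476 regions with Chr names and 1022 with Gm names. Under the linking rule used, runs of regions kept their spacing in all 20 pairs of chromosomes with equal numbers, and 433 regions with Chr names were linked to a region with a Gm name. The order was the same for 422 links and reversed for 11, all on chromosome 5. The median pair of equal number held 21 links (range 9 to 42). The 380 pairs of unequal number held 0.18 links on average and at most 10, in 8 pairs. These 8 pairs lay among 5 chromosomes (3, 6, 9, 13 and 19), and 4 of them were mirrored: 3 with 6 held 10 and 8 links, and 6 with 19 held 9 each way. If both sets list the same places, a link in a pair can recur in its mirror, so mirrored pairs are not separate support. Each of the 8 pairs held chromosome 6 or 13, which had the most regions with Chr names (104 and 111). The linking rule was chosen after the data were examined, from 10 settings that gave 292 to 516 links. At 6 of these settings at least 1 pair of equal number had no link, and the regions of replicate 1 alone gave 27 links, in 3 pairs. Positions differed between the sets by a median of 268 kb and by up to 4476 kb. The reach of the lists differed as well: the last region of chromosome 11 lay at 34.4 Mb under the Chr names and at 38.9 Mb under the Gm names. The leading region of chromosome 10 was linked to Gm chromosome 10, 42036754 to 42037324, which held the fifth rank among shared regions, and 4 linked pairs had both members among the 20 leading regions. Counting each linked pair as 1 place left 2074 places, of which 786 were called in both replicates, or 96.2% of the 817 places of replicate 1 (95% interval 94.7 to 97.4%). The same 786 were 38.5% of the 2043 places of replicate 2 (36.4 to 40.6%). The rule linked 42.4% of the regions with Gm names. Any place listed under both names that it did not link still counts under each name.

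**Figure D3:**
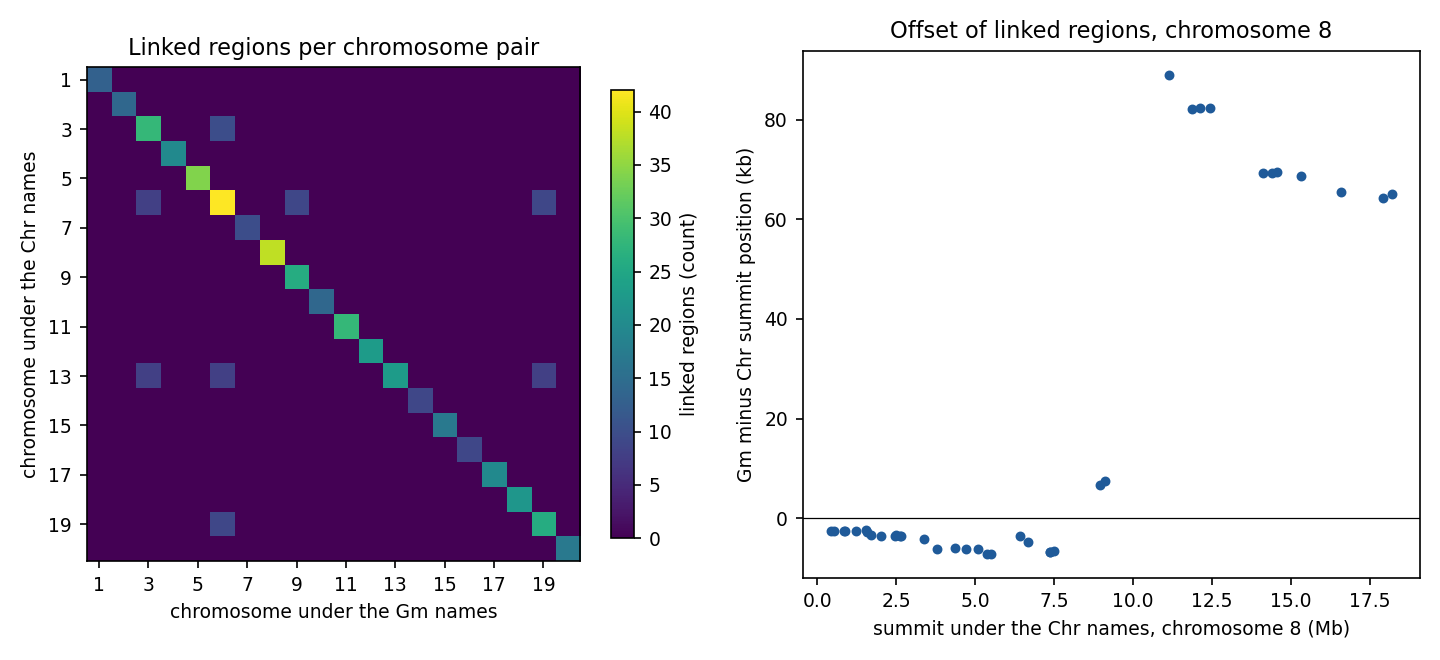
Left, the number of linked regions (colour) for each pair of a chromosome under the Chr names (y axis) and under the Gm names (x axis); right, the distance in kb between linked summits on chromosome 8 (y axis) along the Chr position in Mb (x axis), each point being 1 link. Pairs of equal number hold 9 to 42 links on the diagonal, and pairs of unequal number at most 10.

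Fewer regions carried Gm names than Chr names in both lists. The Gm share was 30.6% in replicate 1 and 41.3% in replicate 2. In replicate 1, 122 of the 433 linked pairs were called under both names, 151 under the Chr name alone and 12 under the Gm name alone. In replicate 2, which supplied most of the regions used for linking, 417 were called under both names, 3 under the Chr name alone and 12 under the Gm name alone. A pair enters this count only if each name was called in at least 1 replicate. Where both were called, summit fragments were more numerous under the Chr name in 106 of 119 untied pairs of replicate 1 (89.1%, 95% interval 82.0 to 94.1%, exact sign test p = 2.7e-19) and in 306 of 403 untied pairs of replicate 2 (75.9%, 71.5 to 80.02%, exact sign test p = 2.6e-26). The median summit held 38 fragments under the Chr name and 28 under the Gm name in replicate 1, and 35 and 30 in replicate 2.

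**Figure D4:**
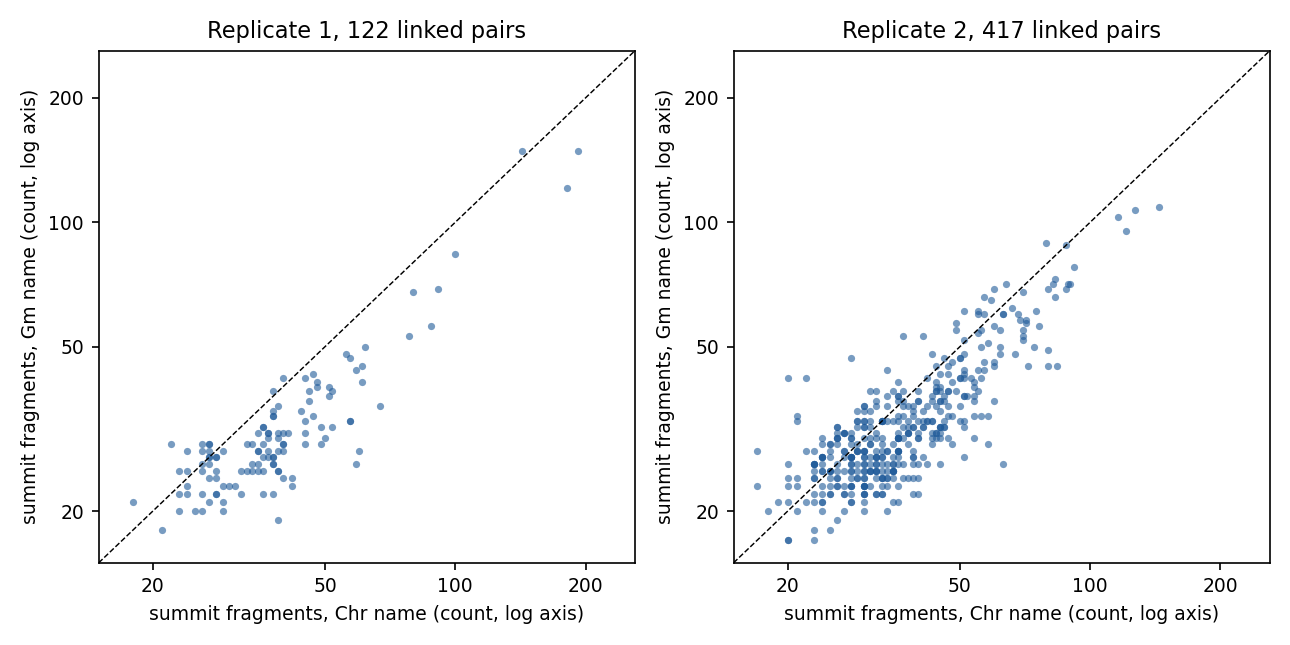
Fragments at the summit under the Chr name (x axis) and the Gm name (y axis) of linked pairs called under both names, in replicate 1 (left, 122 pairs) and replicate 2 (right, 417 pairs), both counts on log axes; the dashed line marks equal counts. Most points lie below the line, 106 in replicate 1 and 306 in replicate 2.

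A small class of regions stood on a high local background. These were 31 regions in replicate 1 and 28 in replicate 2, with a median fold of 1.81 and 2.16, although their median summit held 159 and 115 fragments. In replicate 1, 10 of the 31 were shared under the same name (32.3%, 95% interval 16.7 to 51.4%), against 882 of the 908 other regions (97.1%, 95.8 to 98.1%, two-sided Fisher's exact test p = 1e-22). In replicate 2, 13 of 28 were shared against 879 of 2432 (two-sided Fisher's exact test p = 0.32). Some unshared regions of this class in replicate 1 were linked to a region of the other name that replicate 2 called. For example, the region at 53487445 to 53487664 on Chr chromosome 1 held 140 fragments in replicate 1. Its linked Gm region held 118 in replicate 2. The low share in replicate 1 is therefore in part a change of name. On Chr chromosome 12, 5 such regions of replicate 1 lay between 39187523 and 39193267, and 1 of them was shared. Further regions of the class lay between 39212089 and 39219481 on Gm chromosome 12, and some were linked to these Chr regions. The Fisher's exact tests thus count some places more than once. Without this class, 879 of 908 regions of replicate 1 were shared (96.8%).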

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

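The number of shared regions, their rank agreement and their rank against unshared regions kept their direction and their side of the threshold under the alternatives fixed before the data were examined. The number of shared regions was 874 with a reciprocal overlap of 50%, 837 with summits within 100 bp, 866 with a −log10 q of at least 5, 655 with lists of equal length and 888 on chromosomes only. Among the settings chosen after the data were examined it was 280 with Gm names only, which hold fewer regions by construction, and 786 with linked regions joined. Rank agreement ran from a rho of 0.62 to 0.67, and shared regions outranked unshared regions in each setting. Linked regions numbered from 27 without replicate 2 to 411 without replicate 1, so the links rest on the longer list of replicate 2. They numbered 333 with spacing kept within 250 bp plus 0.5% (in 19 of the 20 pairs of equal number), 535 with 500 bp plus 2%, 372 in chains of at least 10 regions (in 18 pairs) and 516 in chains of at least 6. The 2 looser settings also raised the chance level, to 43.2 and 41.9 links expected over 20 pairs against 3.63 at the reported setting. Shared regions with a neighbour within 10 kb numbered 23 with Gm names only. Taking each list alone gave 66 such regions without replicate 2 and 146 without replicate 1, because each list holds more regions than the shared set; the chance level for the latter was 72.0. Leaving out 1 of the 2 replicates leaves no shared regions to count, so sharing and rank agreement have no such value. The alternatives for transcription starts, motifs and gene lists were not run, since those results need a genome of the same build. No paired analysis was possible because the design holds 1 group. Depth limits the lists to summits of about 16 or more fragments at the lowest background, so a region absent from a list is not shown to be unbound. Regions of replicate 2 that were not shared under the same name reached a −log10 q of 45.8 with Gm names and 33.3 with Chr names. Some of them were linked to a region of the other name that replicate 1 called. For example, a Gm region of chromosome 13 held 61 fragments in replicate 2, and replicate 1 called only its linked Chr region, with 43. Why replicate 1 lacked the remaining regions was not tested region by region.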

Other observations

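Scaffolds outside the chromosomes held 4 regions in replicate 1 and 9 in replicate 2, and all 4 of replicate 1 were shared. On scaffold 28, 3 shared regions lay close together, the strongest with a fold of 8.23 in replicate 1 and 10.96 in replicate 2. The other shared scaffold region stood on a high local background, with a fold of 1.81 in replicate 1 and 1.42 in replicate 2.

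For 3 patterns, technical explanations were tested. The tests of the 2 coordinate systems, of duplicated segments (both tests) and of sequencing depth were chosen after the result was seen and the other tests before, although those on linked regions use a linking rule chosen after the data were examined.

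The runs of regions that recur under the Chr and Gm names may be 1 genome listed in 2 coordinate systems, as from an index with 2 assemblies side by side. The median pair of chromosomes with equal numbers held 21 links and no pair of unequal numbers over 10, under a rule chosen for that gap. At the first of the 10 settings, tried before any choice, the values were 21.5 and 16. That setting also gave 837 links over the 380 pairs of unequal number, or 64.4% of all its links. Its 20 pairs of equal number held 462. Duplicated segments that join different chromosomes are argued against as the source of links between equal numbers. The first setting gave 462 such links and at most 203 with the Gm numbers shuffled (one-sided permutation p = 1e-05 at each of the 10 settings, the smallest that the shuffles can give). Segments duplicated within 1 chromosome would also link equal numbers, so the shuffles cannot weigh on them. For the links between unequal numbers duplicated segments stay open. These links were 13.7% of all links under the rule used, above the limit of 10% set for the test, and 2.61 to 64.4% over the 10 settings. That their 8 pairs lay among 5 chromosomes cannot decide this. Each pair held chromosome 6 or 13, which had the most regions with Chr names. Which assemblies these are was not tested, nor was another biological explanation.

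The list of replicate 2 was 2.62 times as long as that of replicate 1. More sequenced fragments are argued against, since the background of replicate 2 was 1.04 times that of replicate 1. A looser threshold is argued against, since asking at least 17 fragments of both lists still left a ratio of 2.62. Lower enrichment over background in replicate 1 is in line with the values: of the 199 shared regions among its 200 strongest, 86.9% had a higher fold in replicate 2 (95% interval 81.4 to 91.3%), although choosing them by their strength in replicate 1 works against this. Whether such a difference comes from the precipitation or from the embryos stays open, because each replicate is 1 list.

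Regions with Chr names outnumbered those with Gm names. Whether sequence found only under the Chr names accounts for this stays open: between neighbouring links, the median percentile of Chr regions without a Gm partner minus that of linked ones was -24.3 in replicate 1 (28 regions, two-sided permutation p = 0.024) and -37.9 in replicate 2 (171 regions, permutation p = 1e-05), but kept spacing leaves out most such sequence, and only 177 of the 1043 Chr regions without a partner lay between links. For Gm regions the difference was -24.2 in replicate 2 (46 regions, permutation p = 0.0019) and 21.01 in replicate 1 (6 regions, permutation p = 0.16), and Chr and Gm were not tested against each other. An uneven division of fragments between 2 listings of 1 place would give 1 listing more fragments. The Chr listing had more in 75.9% of untied linked pairs of replicate 2. Pairs called under 1 name were 151 Chr and 12 Gm in replicate 1, and 3 Chr and 12 Gm in replicate 2. The counts of replicate 2 cannot weigh on this division. There, a pair called under 1 name alone needs a call of the other name in replicate 1. Linked regions called in replicate 1 were 273 Chr and 134 Gm. Whether an uneven division accounts for the excess of Chr regions, and any biological explanation, was not tested.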
